A study of Mus musculus with 9 samples.

How the data were processed

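The data were RNA-seq of 9 lung samples of 12-week-old mice, 3 in each of the groups control, LPS and LPS plus PD, from libraries enriched for polyadenylated RNA per the labels. The values used were FPKM (fragments scaled to transcript length and to the mapped fragments of the library) per gene and library, as deposited in 1 table of 32114 genes. Per the submitters' processing notes, bcl2fastq, FastQC, HISAT2 and StringTie were used with the GRCm38 genome. Their versions and settings, the strandedness of the libraries and the treatment of reads that fit several copies of a gene are not given in the sources used here. Each column was joined to its sample by the column name that the sample's description repeats, and 0 columns were left over. The labels call PD by its initials, and it was read as the panaxadiol of the series title.

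The values were checked against the annotation. Of the 32114 gene identifiers 32025 (99.7%) were in GENCODE M21, 95.7% with the same coordinates, and 18229 genes were protein-coding. The deposited FPKM values moved in steps, and with the exon lengths of 7782 genes of a single exon the depth at which the steps became whole reads was found for each library. At that depth between 97.2% and 97.5% of the values under 100 reads lay within 0.05 of a whole read. The depths found this way were 15.2 to 19.2 M reads. They describe the step of the values and were not taken from a label. A symbol shared by several identifiers (38 symbols) was kept as separate genes.

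Genes with a mean FPKM of at least 0.5 over the 9 libraries were tested (16227 genes). The values were taken as log2(FPKM + 1) with no further scaling. A linear model with 1 mean per group was fitted to all 9 libraries in limma 3.58.1 (R 4.3.3), with moderated variances that followed a trend with expression (prior df 2.83, median standard error 0.198). The 3 pairwise comparisons were tested with Benjamini-Hochberg adjustment over the genes at a threshold of 0.05. A pseudocount of 1 shrinks the folds of lowly expressed genes. Gene lists were tested with camera from limma at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of 41 lists with 612 symbols, 4 of which were not in the table, 40 had at least 3 measured members and were tested. The list of thymus and lymphoid precursor genes had fewer and was left out. Camera compares a list with all other genes, and its preset correlation is small. It was therefore run again with the correlation estimated for each list, and fry, which tests whether a list's own genes move on balance in 1 direction, was run beside it. The first 2 lists came from the series title. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

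The groups, tests, filter, gene lists and the rule for naming genes were chosen before the data were examined. The rule named, for each comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose 3 libraries of each group did not overlap, without predicted genes, pseudogenes and antigen receptor segments. Where no gene passed, it named the 10 genes with the smallest p as values. For each list it named up to 4 members past the threshold with the largest difference, or the pair with the smallest p as values, and in every comparison the 5 genes Tnf, Tnfrsf1a, Tnfrsf1b, Il7 and Il7r. Genes named outside the rule are marked as chosen after their values were seen.

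The fit was tested on simulated data with the means and spread of these libraries and 100 genes changed by each of 2 sizes. Of the genes changed 2-fold it recovered 44% for LPS against control, 56% for LPS plus PD against LPS and 50% for LPS plus PD against control, and of those changed 4-fold 84%, 85% and 83%. False calls made up 5.9%, 7.2% and 4.3% of the calls. In each comparison of these 16227 simulated genes camera called the 1 shifted list and 0 of 39 unchanged ones. The changed genes had a mean log2(FPKM + 1) of at least 1, and the change was added on that scale. The noise was normal with 1 spread per gene for all groups, so no simulated library stood apart. The shares recovered therefore do not apply to lower genes or to folds of FPKM. The simulated genes varied independently of each other. In the real lists the estimated correlation was often far above the preset, at 0.741 for neutrophil markers and 0.825 for interferon-stimulated genes. The simulation therefore does not test the list calls made with the preset correlation.

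The alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at a mean FPKM of 5, median-ratio scaling, quantile normalization, equal FPKM totals, a fit of only the 6 libraries compared, no variance trend, array weights, the replicate number as a block, and leaving out each library in turn. A group left with 2 libraries shares the spread of the other groups. Rescaling without the mitochondrial genes and voom on the reads recovered from the FPKM steps were chosen after seeing the data. Because the LPS libraries enter both the difference from control and the difference with PD, the share of opposite signs was set beside the share in 100 simulated draws of unchanged groups. Each draw shuffled the deviations of the libraries from their group means, which sum to 0 within a group. A draw that puts the deviations of 1 group together gives a mean of 0 and ties the differences to each other. The extremes of these draws can therefore come from the shuffling.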

Results

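Polyadenylated RNA of mouse lung was measured in 3 groups with 3 libraries each. Control mice received sterile saline, the LPS group received bacterial lipopolysaccharide at 50 µg per mouse, and the LPS plus PD group received LPS and also inhaled an aerosol of PD at 10 mg/mL. LPS is the endotoxin of Gram-negative bacteria and a standard trigger of acute lung inflammation. PD is read here as panaxadiol, the ginseng sapogenin that the series title names. The mice were 12 weeks old, and female by the labels, which the sex-linked transcripts given below contradict. The design text speaks of 6 animals per group. Which animals the 3 libraries of a group came from, how LPS was given and when the lungs were taken are not given in the sources used here. The labels call the libraries separate samples without saying that each is a separate animal, so the p-values below measure only the spread between these libraries, which may be technical. Depth was 16.8, 15.7 and 17.3 M reads in control replicates 1, 2 and 3. It was 16.7, 15.2 and 17.2 M reads in LPS replicates 1, 2 and 3, and 17.3, 16.4 and 19.2 M reads in LPS plus PD replicates 1, 2 and 3. LPS replicate 2 stood apart: its highest correlation with any other library, across genes, was 0.914, while each of the other 8 libraries had a correlation of at least 0.971 with another one. Genes are not independent replicates, so these correlations describe the libraries and test nothing.

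The comparison of LPS with control asked what endotoxin did to the lung. Acute-phase, neutrophil, chemokine and glucocorticoid-responsive transcripts were higher after LPS, and transcripts of ciliated and secretory airway cells, heart muscle, cell division and the mitochondrial genome were lower, the last with 0 of 13 genes past the threshold. These group results come from camera with a preset correlation, and each had an adjusted p = 0.384 with an estimated correlation. The adjustment over the lists gave that 1 value to unadjusted p from 0.0147 (acute-phase) to 0.192 (mitochondrial genome). Fry called all of these lists except those of secretory airway cells (fry adjusted p = 0.0658) and the mitochondrial genome (fry adjusted p = 0.0641). Saa3, a serum amyloid A protein made in inflamed tissue (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700 in GRCm38, minus strand), went from 3.32 ± 1.68 FPKM in control to 289.6 ± 173 FPKM in LPS (SD, n = 3). Lcn2, lipocalin 2, a secreted protein that withholds iron from bacteria (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, minus strand), went from 29.4 ± 7.48 to 763 ± 587 FPKM. The largest falls were in Myl7, an atrial myosin light chain, from 238.6 ± 156 to 14.8 ± 12.7 FPKM, and in Scgb3a2, a secretoglobin of airway club cells, from 1293 ± 702 to 123 ± 91.5 FPKM. In limma 613 of 16227 genes differed, 200 higher and 413 lower, and 571 of the 613 were protein-coding. Of all 613 genes 404 differed at least 2-fold on the log2(FPKM + 1) scale, on which the fold of a lowly expressed gene is understated.

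Saa3 rose by 5.97 ± 0.70 (log2 difference ± SE, adjusted p = 0.013) and Lcn2 by 4.42 ± 0.49 (adjusted p = 0.0127). The other 6 of the 8 largest rises were Ly6i, a surface protein of the Ly6 family, by 4.89, Il1b, the cytokine interleukin 1 beta, by 4.15, and Slfn4, a schlafen gene of myeloid cells, by 4.13, followed by Cxcl2, a neutrophil chemoattractant, by 3.99, Stfa2l1, a stefin of neutrophils, by 3.97, and Wfdc17, a secreted protein of activated macrophages, by 3.93. Their adjusted p lay between 0.0276 and 0.0481. Their size and rank rested in part on LPS replicate 2: Il1b stood at 30.0, 458 and 27.7 FPKM in LPS replicates 1, 2 and 3, and without LPS replicate 2 the differences were 3.95 for Ly6i, 2.83 for Il1b, 2.90 for Slfn4, 2.82 for Cxcl2, 3.37 for Stfa2l1 and 3.07 for Wfdc17. Ly6i, Stfa2l1 and Slfn4 have close copies in their gene families, so reads shared between copies leave their levels uncertain. Myl7 fell by 4.30 ± 0.90 (adjusted p = 0.0441) and Scgb3a2 by 3.60 ± 0.80 (adjusted p = 0.0476). The other 6 of the 8 largest falls were Sln (sarcolipin), Tcap (telethonin), Cox8b, Myl4 and Mb (myoglobin), which are muscle genes, and Krtap17-1, a keratin-associated protein, with log2 differences from -3.43 to -3.27. The groups did not overlap in 37.6% of the genes tested, against 10% by chance, and 4857 genes had an unadjusted p below 0.05 against 811 by chance. The count of 613 rested on single libraries: it was 8 without control replicate 2, 32 without control replicate 1, 210 without control replicate 3, 43 without LPS replicate 1, 1037 without LPS replicate 3, 25, 174 and 79 without LPS plus PD replicates 1, 2 and 3, and 605 without LPS replicate 2. A fit of only the 6 libraries compared gave 9. Of the 59 changed genes that the naming rule picked in this comparison, 4, 1 and 21 still passed without control replicates 1, 2 and 3, 7, 51 and 48 without LPS replicates 1, 2 and 3, and 7, 21 and 13 without LPS plus PD replicates 1, 2 and 3. None changed sign in any of these 9 fits.

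**Figure D1:**
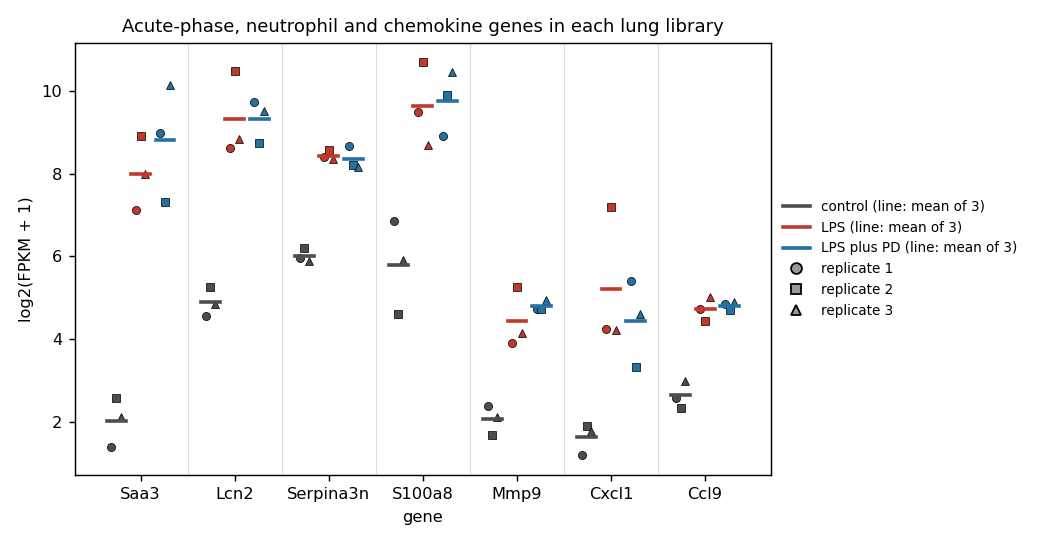
Level of 7 genes in each of the 9 lung libraries as log2(FPKM + 1), with 1 point per library, its shape giving the replicate number, and a line at the mean of 3. Saa3 averaged 3.32 FPKM in control, 289.6 in LPS and 597 in LPS plus PD, and LPS replicate 2 (square) had the highest LPS value of Saa3, Lcn2 and Cxcl1.

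Acute-phase and secreted host-defence proteins were called higher as a group. Of 18 measured genes 7 rose, 13 adjusted over the list alone, with a median log2 difference of 1.70 (camera adjusted p = 2.75e-11). Besides Saa3 and Lcn2 they included Saa1, by 3.38, and Serpina3n, a protease inhibitor of the acute phase, by 2.42 ± 0.19 (adjusted p = 0.00719), which kept its call without each of the 9 libraries. Saa1 has near-identical copies, which makes its level uncertain. Neutrophil markers were called higher too: 10 of 20 measured genes passed, and adjusted over the list alone 18 rose and 1 fell, with a median of 2.86 (camera adjusted p = 3.22e-13). S100a8, a calprotectin subunit that neutrophils carry in bulk, rose from 66.1 to 928 FPKM (log2 3.82, adjusted p = 0.0347), and Il1r2, the decoy receptor of interleukin 1, by 3.45. Among 6 measured genes of neutrophil precursor granules Chil1, a chitinase-like protein that epithelium and macrophages also make, rose by 3.22 and Ngp by 2.51, and the same 2 passed adjusted over the list alone (median 0.57, camera adjusted p = 0.0127). Of 15 monocyte and recruited macrophage markers Ly6i and Itgam (integrin alpha M, by 2.53) rose, 11 adjusted over the list alone, with a median of 2.30 (camera adjusted p = 9.31e-08). Of 15 NK and cytotoxic cell markers only the chemokine gene Ccl5 rose (by 3.13), 5 adjusted over the list alone, with a median of 1.14 (camera adjusted p = 3.47e-07). The size of the NK median was unsure: it was 0.31 with array weights and larger at a mean FPKM of at least 5, and the list was called in both. All 5 of these calls were lost when the correlation between genes was estimated, each with an adjusted p = 0.384 with an estimated correlation. Fry called the acute-phase (fry adjusted p = 0.0108), neutrophil (0.0378) and precursor granule (0.0284) lists. It did not call the monocyte (0.0698) and NK (0.0929) lists. Without LPS replicate 2 the monocyte median was 1.14 and the list was still called (camera adjusted p = 2.32e-09).

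Signalling and effector lists moved with the immune cell markers. Of 26 measured chemokines 7 rose, 10 adjusted over the list alone, with a median of 2.13 (camera adjusted p = 1.63e-09), led by Cxcl2, Cxcl1 (by 3.59), Ccl5 and Cxcl3, of which the Cxcl genes attract neutrophils. Of 16 pro-inflammatory cytokines Il1b and Csf2 (the growth factor GM-CSF, by 1.16) rose, 4 adjusted over the list alone, with a median of 1.19 (camera adjusted p = 2.47e-05). Of 26 genes of TNF and NF-kB signalling Birc3 (an inhibitor of apoptosis, by 1.66) and Map3k8 (a kinase upstream of ERK, by 1.34) rose, while adjusted over the list alone 9 rose and 1 fell, with a median of 0.71 (camera adjusted p = 3.02e-07). None of 20 genes of endotoxin sensing and the inflammasome and none of 28 interferon-stimulated genes passed over all genes or adjusted over the list alone, yet both lists were called as groups, with medians of 0.90 (camera adjusted p = 3.02e-07) and 1.74 (camera adjusted p = 1.96e-09). Irf7, the regulator of interferon genes, differed by 2.55 ± 0.61 (adjusted p = 0.0551). Each of these 5 calls had an adjusted p = 0.384 with an estimated correlation. Fry called the chemokines (fry adjusted p = 0.0284). It did not call the cytokines (0.132), NF-kB signalling (0.136), endotoxin sensing (0.132) or the interferon-stimulated genes (0.182). LPS replicate 2 carried much of their size: mean log2 levels above control in LPS replicates 1, 2 and 3 were 1.15, 4.02 and 0.33 for interferon-stimulated genes, 0.59, 2.74 and 0.60 for cytokines and 1.08, 3.20 and 1.38 for chemokines. Without LPS replicate 2 the medians were 0.66 for interferon-stimulated genes, 0.57 for cytokines, 1.17 for chemokines, 0.31 for NF-kB signalling and 0.36 for endotoxin sensing, and all 5 lists were still called.

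The list mean of the glucocorticoid-responsive genes lay above control by similar amounts in all 3 LPS libraries, at 1.65, 1.46 and 1.41. Of 16 measured genes 5 rose, 13 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 5.22e-10, adjusted p = 0.384 with an estimated correlation, fry adjusted p = 0.0278). Besides Lcn2, which the acute-phase list also holds, they were Angptl4, an inhibitor of lipoprotein lipase, by 2.38, Fkbp5, a chaperone of the glucocorticoid receptor, by 1.79, Cdkn1a, the cell cycle inhibitor p21, by 1.67, and Sgk1, a kinase named after its values were seen, by 1.44. Of 14 genes of IL-7 signalling through JAK and STAT5 only Pim1, a serine/threonine kinase and STAT target shared by many cytokines, rose (by 1.92), while adjusted over the list alone 5 rose and 1 fell, with a median of 0.29 (camera adjusted p = 0.00348, adjusted p = 0.384 with an estimated correlation). Of 11 dendritic cell and MHC class II genes Ccr7, the chemokine receptor that guides cells to lymph nodes, rose by 1.02, while adjusted over the list alone 1 rose and 1 fell, with a median of 0.69 (camera adjusted p = 0.036, adjusted p = 0.384 with an estimated correlation). That last call was lost without control replicate 2 (camera adjusted p = 0.104), LPS replicate 2 (0.216) and LPS plus PD replicates 1 (0.0634) and 3 (0.0737), and under each of 3 other scalings of the libraries, where its camera adjusted p was 0.0933, 0.057 and 0.101. The median ranged from 0.16 without LPS replicate 2 to 1.06 without LPS replicate 1. It was 0.45 without control replicate 2, and its sign turned with array weights (-0.03, camera adjusted p = 0.331).

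**Figure D2:**
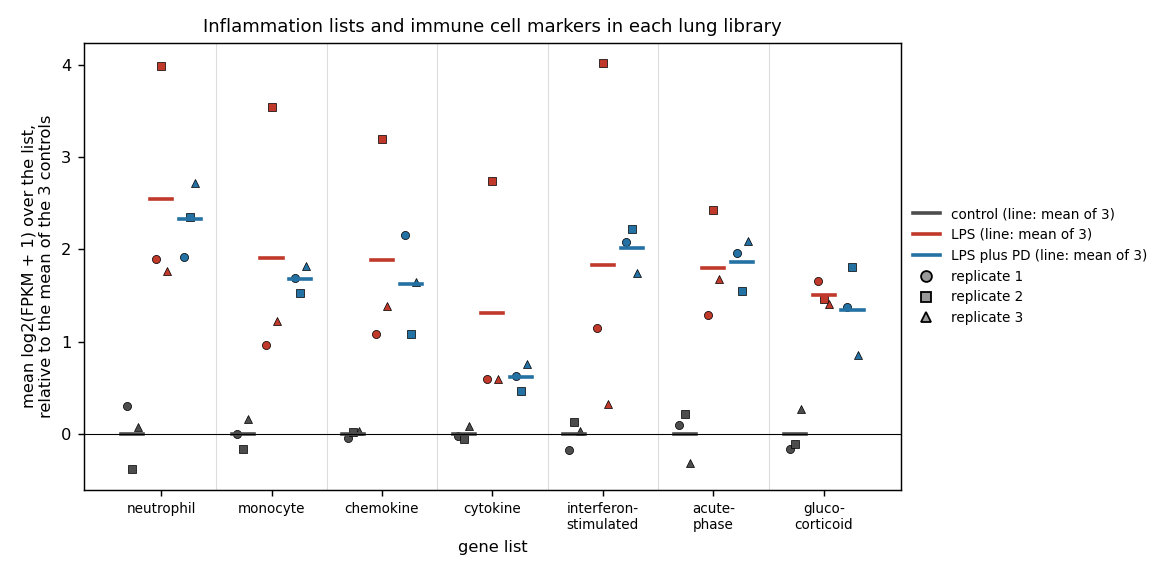
Mean log2(FPKM + 1) of 7 gene lists in each library, relative to the mean of the 3 controls, with 1 point per library, its shape giving the replicate number, and a line at the mean of 3. LPS replicate 2 (square) lay at 4.02 for interferon-stimulated genes, with LPS replicates 1 and 3 at 1.15 and 0.33 and the LPS plus PD libraries from 1.75 to 2.22.

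The series title names TNF, IL-7 and their receptors. Tnf, which encodes tumor necrosis factor (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007, minus strand), stood at 0.254, 0.66 and 0.53 FPKM in the controls and at 3.18, 83.8 and 4.52 FPKM in LPS replicates 1, 2 and 3. Its log2 difference of 3.09 ± 0.97 missed the threshold (adjusted p = 0.0873) and was 1.71 without LPS replicate 2, where it passed (adjusted p = 0.0294). Tnfrsf1a, the TNF receptor found on most cells, rose from 63.0 ± 5.97 to 99.8 ± 12.8 FPKM (log2 0.65 ± 0.15, adjusted p = 0.0498). Leaving out any one of the 9 libraries ended this call, with log2 differences from 0.55 to 0.72. Tnfrsf1b, the TNF receptor mainly of immune and endothelial cells, differed by 2.10 ± 0.59 (adjusted p = 0.0698) and by 1.31 without LPS replicate 2, where it passed (adjusted p = 0.0415). The 3 genes were called as a list, 1 over all genes and 3 adjusted over the list alone, with a median of 2.10 (camera adjusted p = 0.00234, adjusted p = 0.384 with an estimated correlation), or 1.31 without LPS replicate 2. Il7, a stromal cytokine that keeps lymphocytes alive, was expressed at 0.85 ± 0.08 FPKM in control and 0.64 ± 0.23 in LPS (log2 -0.18 ± 0.14, adjusted p = 0.411). Il7r, its receptor on lymphocytes, differed by 0.75 ± 0.26 (adjusted p = 0.106), at a mean of 1.30 FPKM in control and 3.00 FPKM in LPS, and by 0.47 without LPS replicate 2 (adjusted p = 0.192). The list of Il7, Il7r and Il2rg had no member past the threshold over all genes or adjusted over the list alone and was not called (median 0.75, camera adjusted p = 0.188). Since the series title chose both lists, they are not independent evidence of a direction.

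**Figure D3:**
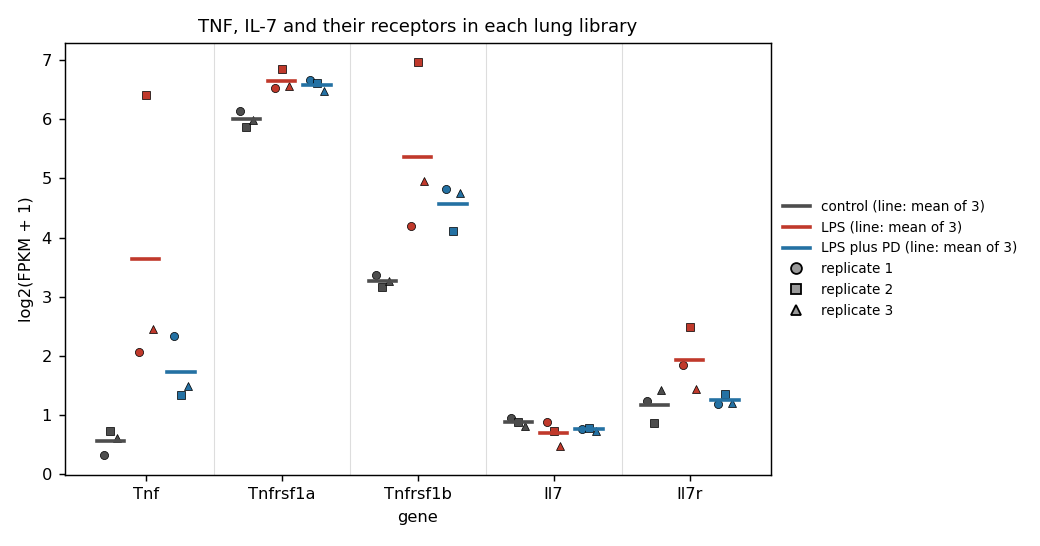
Level of Tnf, its receptors Tnfrsf1a and Tnfrsf1b, Il7 and its receptor Il7r in each of the 9 libraries as log2(FPKM + 1), with 1 point per library, its shape giving the replicate number, and a line at the mean of 3. Tnf was at 83.8 FPKM in LPS replicate 2 and at 3.18 and 4.52 FPKM in LPS replicates 1 and 3, and Tnfrsf1a separated control from both LPS-exposed groups.

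Airway, muscle and proliferation genes were lower after LPS. Of 12 measured heart muscle genes, which lung libraries hold where cardiac muscle of the pulmonary veins or heart tissue is in the piece, 10 fell, 11 adjusted over the list alone, with a median of -3.02 (camera adjusted p = 5.92e-08) and Myl7, Sln, Myl4 and Mb as the largest falls. The controls themselves spread widely on this list, at 0.15, 0.93 and -1.08 around their mean. Of 16 ciliated cell markers Tppp3 fell by 2.07, Dnali1 by 1.61 and Dnah5 by 0.91, the latter pair being dynein genes of the cilium, and 15 fell adjusted over the list alone, with a median of -1.15 (camera adjusted p = 4.59e-07). Of 13 club and secretory airway cell markers Scgb3a2 fell, 8 adjusted over the list alone, with a median of -1.64 (camera adjusted p = 0.00123). Of 18 cell division genes Ube2c fell by 1.30, Cdk1, the kinase that starts mitosis, by 1.18, Ccnb1, its cyclin B1 partner, by 1.03 and Tpx2, a spindle factor, by 0.91, and 17 fell adjusted over the list alone, with a median of -0.85 (camera adjusted p = 9.54e-08). None of 13 mitochondrially encoded genes passed over all genes, 9 fell adjusted over the list alone, and the median was -0.98 (camera adjusted p = 0.000132). These 5 calls each had an adjusted p = 0.384 with an estimated correlation. Fry called the heart muscle (fry adjusted p = 0.0284), ciliated cell (0.043) and cell division (0.0278) lists. It did not call the club and secretory cell (0.0658) and mitochondrial (0.0641) lists. The 23 ribosomal protein genes were lower without exception, with none past the threshold over all genes or adjusted over the list alone and a median of -0.47 (camera adjusted p = 0.000439, adjusted p = 0.523 with an estimated correlation), which was -0.31, -0.36 and -0.27 under the 3 other scalings. Scaling mattered for this side: the median gene of all tested lay at -0.11 as deposited, and at 0.01, -0.03 and 0.04 under the median-ratio, quantile and equal-total scalings, where the calls were 149 higher and 178 lower, 246 and 368, and 204 and 187.

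Adipocyte genes and fibroblast genes were called lower with less weight. Of 9 adipocyte genes Lpl, the lipoprotein lipase that macrophages also make, went the other way and rose by 1.55. Adjusted over the list alone 1 rose and 6 fell, with a median of -1.38 (camera adjusted p = 0.0417, adjusted p = 0.609 with an estimated correlation). Of 16 fibroblast and matrix genes Pdgfra, a growth factor receptor of mesenchymal cells, also went the other way and rose (adjusted p = 0.0359). Adjusted over the list alone 1 rose and 6 fell, with a median of -0.79 (camera adjusted p = 0.0473, adjusted p = 0.658 with an estimated correlation). The adipocyte call was lost in 6 of the other alternatives. In 3 of these the fall was much larger: the median was -2.13 at a mean FPKM of at least 5 (camera adjusted p = 0.471), -3.24 with voom on recovered reads (0.12) and near that with a pseudocount of 0.01 (0.0501). It was also lost without control replicate 1 (camera adjusted p = 0.107), control replicate 2 (0.0988), LPS replicates 1, 2 and 3 (0.0989, 0.0555 and 0.0595) and LPS plus PD replicates 2 and 3 (0.0555 and 0.0516). The fibroblast call was lost with array weights (0.106), in 4 more of the alternatives, and without control replicate 1 (0.166), LPS replicate 2 (0.216, median -0.41) and LPS plus PD replicates 2 and 3 (0.0555 and 0.055). Camera did not call the 18 other lists tested. Among them fry called the 7 plasma cell markers lower (median -0.68, fry adjusted p = 0.0363, camera adjusted p = 0.181), with 3 that fell over all genes and 4 adjusted over the list alone. In the 18 lists Pdpn, podoplanin of alveolar type 1 cells, rose by 1.01 and Atp6v0d2, a proton pump subunit of macrophages, by 0.73. The plasma cell genes Fkbp11, Derl3 and Sdc1 fell by 1.30, 1.15 and 0.99. Gsta2, a glutathione transferase, fell too (adjusted p = 0.0467), and Cyp51, an enzyme of cholesterol synthesis, fell by 0.83 (adjusted p = 0.0476). T cell markers (median 0.03, camera adjusted p = 0.319), B cell markers (0.03, 0.441), alveolar type 2 markers (-0.03, 0.505) and endothelial markers (0.17, 0.0542) had no member past the threshold over all genes or adjusted over the list alone. Small medians here can hide libraries that moved apart: list means in LPS replicates 1, 2 and 3 were 0.58, -0.70 and 0.68 for endothelial and 0.189, -0.548 and 0.215 for alveolar type 2 markers.

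The comparison of LPS plus PD with LPS asked what the inhaled compound changed in the endotoxin-exposed lung. No single gene passed in limma. Tnf averaged 2.47 ± 1.40 FPKM with PD against 30.5 ± 46.2 FPKM with LPS alone, and the 3 PD libraries (4.08, 1.52 and 1.81 FPKM) overlapped LPS replicates 1 and 3 (3.18 and 4.52 FPKM). Saa3 stood at 597 ± 492 FPKM with PD and 289.6 ± 173 FPKM without, and S100a8 at 947 ± 460 and 928 ± 646 FPKM. At the level of gene groups, mitochondrially encoded, T cell and B cell transcripts were lower with PD, and heart muscle, alveolar macrophage and alveolar type 2 transcripts were higher, by camera with a preset correlation only.

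Of 16227 genes tested 0 passed in limma, 653 had an unadjusted p below 0.05 against 811 by chance, and the groups did not overlap in 8.0% of genes against 10% by chance. A fit with voom on recovered reads and a fit on equal library totals also gave 0. Median-ratio scaling and quantile normalization called Gm24391, a small nuclear RNA locus listed at 0 FPKM in the 6 control and PD libraries and at 2.35, 1.29 and 1.71 FPKM in LPS replicates 1, 2 and 3, and array weights called it together with Gm16464, a pseudogene. Both were named after their values were seen, and a locus of this length is poorly measured in such libraries. In simulated data with the spread of these libraries, the same fit of this comparison recovered 56% of genes changed 2-fold and 85% of those changed 4-fold. These shares hold for genes with a mean log2(FPKM + 1) of at least 1 and for changes on that scale. They do not apply to lower genes, and no simulated library stood apart as LPS replicate 2 did. Once predicted genes, pseudogenes and antigen receptor segments were set aside, as the naming rule does, the 10 genes with the smallest p all had adjusted p = 0.811. Of these P4ha3, a collagen prolyl hydroxylase, was at 2.05 ± 0.21 FPKM with LPS and 0.52 ± 0.24 with PD (log2 -1.01 ± 0.17). Lif, the cytokine leukemia inhibitory factor, was at 4.58 ± 0.62 and 2.05 ± 0.40 FPKM (log2 -0.87 ± 0.16). Rbm3, a cold-inducible RNA-binding protein, stood at 34.6 FPKM in control, 55.4 with LPS and 33.6 with PD (log2 -0.70 ± 0.13), and Btla, an inhibitory receptor of lymphocytes, differed by -1.10. Trim5 and Sumo2 differed by 2.08 and 1.63, both with close copies in the genome that leave their levels uncertain. The muscle genes Tcap and Cox7a1 differed by 2.79 and 1.75, Ear1, an eosinophil-associated ribonuclease of alveolar macrophages with several near copies, by 1.85, and mt-Nd4l, a mitochondrially encoded subunit of respiratory complex I, by -1.52.

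Tnf differed between LPS plus PD and LPS by -1.92 ± 0.97 (adjusted p = 0.866), and by -0.54 without LPS replicate 2. Tnfrsf1a differed by -0.07 ± 0.15 (adjusted p = 0.936), at 99.8 ± 12.8 and 95.0 ± 6.44 FPKM, and its sign turned without LPS replicate 2 (0.04). Tnfrsf1b differed by -0.80 ± 0.59 (adjusted p = 0.866), or -0.001 without LPS replicate 2. Il7 differed by 0.05 ± 0.14 (adjusted p = 0.947) with its sign turned without LPS replicate 3 (-0.06), and Il7r by -0.68 ± 0.26 (adjusted p = 0.866), or -0.40 without LPS replicate 2. Il7r stood at 2.62, 4.65 and 1.73 FPKM in LPS replicates 1, 2 and 3 and at 1.28, 1.57 and 1.31 FPKM in the PD libraries. The TNF list (median -0.80, camera adjusted p = 0.0641) and the list of IL-7 and its receptor (median -0.23, camera adjusted p = 0.199) were not called and had no member past the threshold over all genes or adjusted over the list alone. Both lists follow the series title and are not independent evidence. The 14 genes of IL-7 signalling were not called either (median -0.07, camera adjusted p = 0.481).

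Camera called 14 lists, 6 higher and 8 lower with PD, and fry and camera with an estimated correlation called 0. Without LPS replicate 2 camera called 18 lists, 11 higher and 7 lower with PD, and 9 of these were among the 14. The smallest camera adjusted p of that fit was 3.72e-34, for a list outside the 14. That fit was not repeated with an estimated correlation or with fry. Of the 14, 7 kept their call and direction. Among these 7, the 13 mitochondrially encoded genes were all lower with PD, and 5 fell adjusted over the list alone (median -0.66, camera adjusted p = 4.22e-13, adjusted p = 0.585 with an estimated correlation). mt-Atp6, a subunit of ATP synthase, stood at 197 FPKM with LPS and 69.0 FPKM with PD. Reads shared with nuclear copies leave the levels of mitochondrially encoded genes uncertain. Of 12 heart muscle genes 11 were higher, 9 adjusted over the list alone (median 1.45, camera adjusted p = 6.09e-09, adjusted p = 0.585 with an estimated correlation), and Myh6, a myosin heavy chain of heart muscle, stood at 5.48 and 22.9 FPKM. Adipocyte genes were also higher, 8 of 9, and were not called (median 0.71, camera adjusted p = 0.0556). Of 13 alveolar macrophage markers 11 were higher, 2 adjusted over the list alone (median 0.57, camera adjusted p = 9.47e-05, adjusted p = 0.463 with an estimated correlation), with Ear1 at 2.78 and 13.6 FPKM and Atp6v0d2 at 9.08 and 13.9 FPKM. Of 14 alveolar type 2 markers 13 were higher, none adjusted over the list alone (median 0.44, camera adjusted p = 2.77e-05), with a median of 0.19 without LPS replicate 2. Sftpa1, surfactant protein A, stood at 714 and 1094 FPKM. Lymphocyte lists were called lower: 12 of 13 B cell markers had lower values, 1 of them past the threshold adjusted over the list alone (median -0.58, camera adjusted p = 2.37e-07). The B cell median was -0.29 without LPS replicate 3, and the call was lost at a mean FPKM of at least 5 (camera adjusted p = 0.214). The type 2 and B cell lists each had an adjusted p = 0.585 with an estimated correlation. Of 16 T cell markers 15 were lower, none adjusted over the list alone (median -0.33, camera adjusted p = 1.14e-05, adjusted p = 0.678 with an estimated correlation). The T cell median was -0.16 without LPS plus PD replicate 2, and the call was lost with array weights (camera adjusted p = 0.0589). Of 14 Nrf2 targets of oxidative stress defence 12 were lower, none adjusted over the list alone (median -0.35, camera adjusted p = 0.000599, adjusted p = 0.585 with an estimated correlation), with Slc7a11, the cystine transporter, at 6.78 and 2.59 FPKM.

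The other 7 calls rested on LPS replicate 2, were each lost with array weights, and had no member past the threshold over all genes. The 16 pro-inflammatory cytokines had a median of -0.59, with 1 gene that fell adjusted over the list alone (camera adjusted p = 9.27e-05, adjusted p = 0.69 with an estimated correlation), and a median of 0.12 without that library (camera adjusted p = 0.881). The cytokine median was -0.91 without LPS replicate 1 and -0.96 without LPS replicate 3, and the call was lost at a mean FPKM of at least 5 (camera adjusted p = 0.523). For the 20 genes of endotoxin sensing and the inflammasome the median was -0.43 (camera adjusted p = 0.000137, adjusted p = 0.75 with an estimated correlation), and without LPS replicate 2 the list was called in the other direction (median 0.20, camera adjusted p = 0.0036). NF-kB signalling went the same way, from a median of -0.21 (camera adjusted p = 0.00825, adjusted p = 0.824 with an estimated correlation) to 0.15 without LPS replicate 2 (camera adjusted p = 0.00881), and was not called without LPS plus PD replicate 2 (camera adjusted p = 0.099). The dendritic cell and MHC class II genes were called lower (median -0.42, camera adjusted p = 0.00717, adjusted p = 0.585 with an estimated correlation) and had a median of -0.03 without LPS replicate 2 (camera adjusted p = 0.973). Fibroblast genes (median 0.46, camera adjusted p = 0.00392), club and secretory cell markers (0.93, 0.0156) and xenobiotic-metabolising enzymes (0.49, 0.00717) were called higher. Their adjusted p with an estimated correlation was 0.75, 0.75 and 0.745. Without LPS replicate 2 their medians were 0.12, 0.38 and 0.12 (camera adjusted p = 0.388, 0.2 and 0.27). Without LPS plus PD replicate 2 their camera adjusted p was 0.0631, 0.175 and 0.178, and the xenobiotic list was also lost without LPS replicate 3 (0.0512). Apart from that 1 cytokine gene, no member of these 7 lists passed adjusted over the list alone. Neutrophil markers (median -0.21, camera adjusted p = 0.208), chemokines (-0.25, 0.19), interferon-stimulated genes (0.14, 0.448), acute-phase proteins (0.13, 0.946) and glucocorticoid-responsive genes (-0.03, 0.653) were not called with all 9 libraries. The small interferon median rested on LPS replicate 2. List means above control were 1.15, 4.02 and 0.33 in LPS replicates 1, 2 and 3 and 2.08, 2.22 and 1.75 in the PD libraries.

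**Figure D4:**
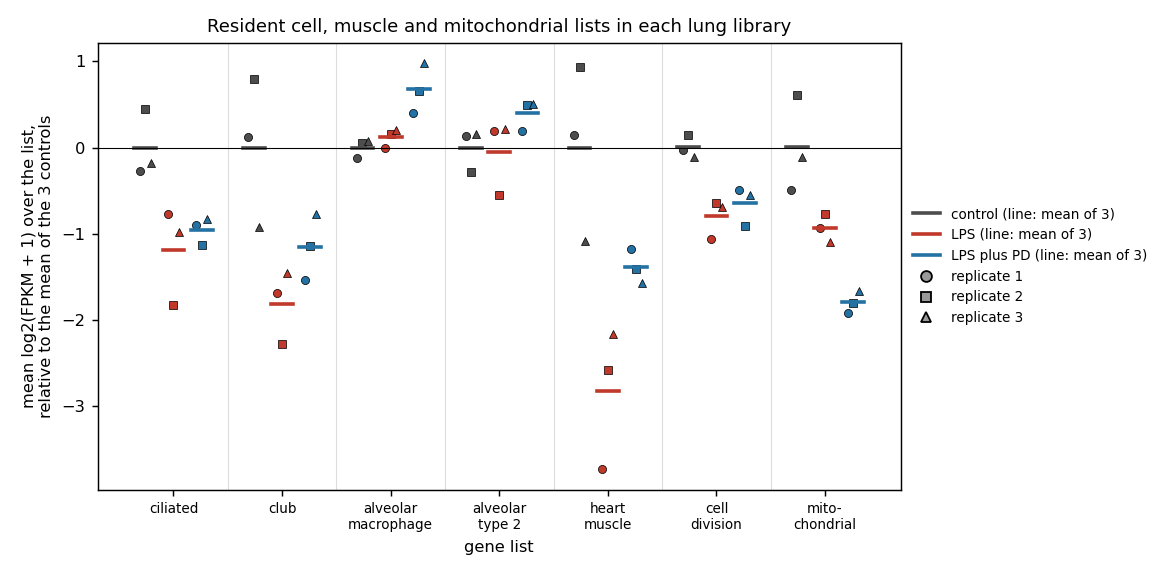
Mean log2(FPKM + 1) of 7 gene lists in each library, relative to the mean of the 3 controls, with 1 point per library, its shape giving the replicate number, and a line at the mean of 3. Mitochondrially encoded genes lay from -1.10 to -0.77 in the LPS libraries and from -1.93 to -1.67 in the LPS plus PD libraries, and heart muscle genes from -3.74 to -2.17 and from -1.57 to -1.18.

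The comparison of LPS plus PD with control asked how far the treated, endotoxin-exposed lung stayed from the saline lung. The acute-phase and neutrophil picture was present here as well: Saa3 rose by 6.78 ± 0.70 (adjusted p = 0.0176), Ly6i by 5.13, Lcn2 by 4.43 and S100a8 by 3.96. Ifitm6, an interferon-induced membrane protein gene, rose by 4.05, Mmp8, the neutrophil collagenase, by 3.92, Saa1 by 3.73 and Irf7, the regulator of interferon genes, from 5.89 ± 1.22 to 97.0 ± 57.5 FPKM (log2 3.65 ± 0.61, adjusted p = 0.0393). Among the 8 largest falls were mt-Nd4l, from 127 ± 52.5 to 16.9 ± 1.53 FPKM (log2 -2.76 ± 0.30, adjusted p = 0.0176), mt-Co3 and mt-Atp6, which encode subunits of cytochrome c oxidase and ATP synthase, with log2 differences of -2.44 and -2.40. All 7 nuclear copies of mitochondrial genes, listed after the data were examined, were lower too (median -2.19). Reads shared with such copies leave the levels of mitochondrially encoded genes uncertain. A gene that the deposited table calls Mcub fell by 2.28, but its identifier (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432) belongs to Areg, amphiregulin, a ligand of the EGF receptor, in the reference gene names. The other 4 were epithelial genes: Sprr1a, a protein of the cornified envelope, Krtap17-1, Ly6g6c and Prss22, a serine protease of airway epithelium, with log2 differences from -2.81 to -2.51.

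In limma 128 genes differed, 61 higher and 67 lower, and 104 of them at least 2-fold. The groups did not overlap in 34.0% of genes against 10% by chance, and 3123 genes had an unadjusted p below 0.05 against 811 by chance. Under the median-ratio and equal-total scalings the split was 81 higher and 53 lower, and 87 and 44. The number of calls rested on single libraries here too: 39, 17 and 46 without control replicates 1, 2 and 3, 59, 1602 and 83 without LPS replicates 1, 2 and 3, and 2, 12 and 5 without LPS plus PD replicates 1, 2 and 3. The LPS libraries enter this comparison only through the shared spread and the filter, and a fit of the 6 libraries compared gave 1193. Of the 31 changed genes that the naming rule picked in this comparison, 15, 10 and 12 still passed without control replicates 1, 2 and 3, 23, 31 and 23 without LPS replicates 1, 2 and 3, and 1, 7 and 3 without LPS plus PD replicates 1, 2 and 3. None changed sign. Tnf differed from control by 1.17 ± 0.97 (adjusted p = 0.535), Tnfrsf1a by 0.59 ± 0.15 (adjusted p = 0.104) and Tnfrsf1b by 1.31 ± 0.59 (adjusted p = 0.267). These 3 passed without LPS replicate 2, with adjusted p of 0.034, 0.0238 and 0.0166. Camera called these 3 genes higher as a list (median 1.17, camera adjusted p = 0.0107, adjusted p = 0.346 with an estimated correlation, fry adjusted p = 0.142). The series title chose that list, so it is not independent evidence. Il7 differed by -0.12 ± 0.14 (adjusted p = 0.663) and Il7r by 0.07 ± 0.26 (adjusted p = 0.905), the latter with its sign turned without control replicate 2 (-0.08). The list of IL-7 and its receptor was not called (median 0.07, camera adjusted p = 0.482). Camera also called IL-7 signalling (median 0.33, camera adjusted p = 0.00286), NF-kB signalling (0.39, 1.4e-05), cytokines (0.59, 0.0181) and endotoxin sensing (0.55, 0.000447) higher. Their adjusted p with an estimated correlation was 0.333, 0.422, 0.542 and 0.5, and fry called none of them. The cytokine call was lost with median-ratio scaling (camera adjusted p = 0.0738).

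Camera called 29 lists against control, 17 higher and 12 lower, and every call was lost with an estimated correlation, where the smallest adjusted p was 0.183. Fry called 11 lists. Of the lists given below it did not call the interferon-stimulated (fry adjusted p = 0.142), ciliated cell (0.0763) and heart muscle genes (0.142). Acute-phase proteins (6 of 18 rose, 12 adjusted over the list alone, median 1.46, camera adjusted p = 2.49e-14) and glucocorticoid-responsive genes (2 of 16, Lcn2 and Cebpd, 13 adjusted over the list alone, median 1.08, camera adjusted p = 1.42e-12) each had an adjusted p = 0.183 with an estimated correlation. Of 20 neutrophil markers 4 rose, 15 adjusted over the list alone (median 2.47, camera adjusted p = 2.43e-15, adjusted p = 0.333 with an estimated correlation). For 26 chemokines the counts were 4, namely Ccl20, Cxcl3, Cxcl13 and Ccl9, and 10 adjusted over the list alone (median 1.87, camera adjusted p = 3.38e-10, adjusted p = 0.252 with an estimated correlation). Of 28 interferon-stimulated genes, all higher, Irf7 rose, 3 adjusted over the list alone (median 2.08, camera adjusted p = 2.18e-13, adjusted p = 0.345 with an estimated correlation). Atp6v0d2 rose by 1.30 among 13 alveolar macrophage markers, 3 adjusted over the list alone (median 0.77, or 0.39 without LPS plus PD replicate 3, camera adjusted p = 8.08e-05, adjusted p = 0.183 with an estimated correlation). On the lower side, 5 of 13 mitochondrially encoded genes fell, 12 adjusted over the list alone, with a median of -1.67 (camera adjusted p = 1.42e-13, adjusted p = 0.252 with an estimated correlation) that stayed between -1.57 and -1.34 under the 3 other scalings. Of 18 cell division genes Ccnb1 fell by 0.91, 14 adjusted over the list alone (median -0.66, camera adjusted p = 3.82e-08, adjusted p = 0.333 with an estimated correlation). None of 16 ciliated cell markers fell over all genes and 13 did adjusted over the list alone (median -0.99, camera adjusted p = 1.72e-07, adjusted p = 0.346 with an estimated correlation). Among 14 Nrf2 targets Srxn1, sulfiredoxin, fell by 1.24, 9 adjusted over the list alone (median -0.66, camera adjusted p = 0.00433, adjusted p = 0.345 with an estimated correlation). Among 14 sterol genes Cyp51 fell by 1.03, 3 adjusted over the list alone (median -0.30, camera adjusted p = 0.00945, adjusted p = 0.333 with an estimated correlation). None of 12 heart muscle genes passed over all genes or adjusted over the list alone (median -1.42, camera adjusted p = 0.000161, adjusted p = 0.422 with an estimated correlation).

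Genes that LPS changed mostly moved the same way in the groups with and without PD, in differences that share the 3 controls. Of the 200 genes that rose and the 413 that fell in LPS, 47 and 50 also passed in the same direction in LPS plus PD, where independent lists of these sizes would share 0.8 and 1.7. The shared numbers were 266 and 233 against 14.1 and 15.8 without LPS replicate 2. The log2 differences from control of all 16227 genes had the same sign in both groups in 82.7% of genes. The median was 65.8% for simulated unchanged groups with the same controls. The simulated range was 0.006% to 99.994%. These limits come from draws that put the deviations of 1 group together, so the range cannot place the observed share. The other simulated ranges in this paragraph come from the same shuffling, so lying inside or outside them decides nothing. Their covariance was 0.287 against a simulated 0.039 (range -0.028 to 0.14), a difference of 0.248. The 3 controls cannot be divided into parts of at least 2 libraries each, so the overlap was not measured with separate controls and part of it may come from sharing them. Of the 613 genes changed by LPS, 610 had the same sign in LPS plus PD and 528 (86.1%) lay closer to control there, with a median ratio of the log2 differences of 0.77. Sharing the controls favours the same sign in these genes, and no simulated same-sign share was made for them. The LPS libraries enter both the difference from control and the difference with PD. Data simulated with no PD effect gave opposite signs in 64.6% of the called genes, with a range of 20.2% to 95.0% over 100 draws that includes the observed share. Without LPS replicate 2 the share was 60.5% (366 of 605 genes) against a simulated 72.1%, and the median ratio 0.92. The covariance of the LPS difference with the PD difference was -0.104 against a simulated -0.048, a difference of -0.056, and the simulated range of -0.125 to 0.013 includes it. With LPS replicate 2 left out it was -0.034 against -0.052 (range -0.087 to 0.006).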

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

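Rescaling without mitochondrial genes and voom on recovered reads were chosen after the data were seen, and all other alternatives before. Across all alternatives and left-out libraries, 1362 list results kept camera's direction and the call, 185 kept camera's direction and lost the call, and 5 reversed. Of the results of named genes called as analysed, 1104 kept both and 861 lost the call. Of those of named genes not called, 497 stayed so with the same sign, 13 gained a call and 7 reversed. The smallest adjusted p for LPS against control was 0.0072. Leaving out 1 library gave 8 to 1037 genes for LPS against control, 2 to 1602 for LPS plus PD against control and 0 for LPS plus PD against LPS, with 19 to 27, 24 to 29 and 14 to 23 lists, and a share of opposite signs from 60.5% to 95.6%. Low genes rested on few reads, since depth was 15.2 to 19.2 M reads.

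For LPS against control the 613 genes became 38 with no filter and 270 at a mean FPKM of 5, where another number of genes was tested, 327 with median-ratio scaling, 391 with equal totals, 9 in a fit of only 6 libraries, 3308 with array weights and 10 with the replicate block. For LPS plus PD against control the 128 genes became 6 with no filter, 1193 in a fit of 6 libraries, 1568 with array weights and 4 with the block. For LPS plus PD against LPS the count of 0 became 1 with median-ratio scaling, 1 with quantile normalization and 2 with array weights. The share of opposite signs, 86.1%, became 82.6% at a mean FPKM of 5, 66.7% with 6 libraries, 78.4% with array weights and 60.0% with the block. Camera with an estimated correlation called 0 lists in each comparison, and fry called 10, 0 and 11 for LPS against control, LPS plus PD against LPS and LPS plus PD against control. Apart from the filters, the cause was not tested.

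Replicate numbers did not pair the libraries. Residual correlations of same-number pairs ranged from -0.183 to 0.192 (median -0.057, 9 pairs), those of other pairs from -0.212 to 0.108 (median 0.038, 18 pairs), and 3 of 9 libraries correlated best with their own number.

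For LPS against control, the median of the dendritic cell and MHC class II genes turned with array weights (-0.029, camera adjusted p = 0.331), while camera's direction held. For LPS plus PD against LPS, array weights reversed Tnfrsf1a (0.048), Tnfrsf1b (0.207), Il7 (-0.049), NF-kB signalling (median 0.177) and endotoxin sensing (0.123). Leaving out LPS replicate 2 reversed Tnfrsf1a (0.038; range over left-out libraries -0.123 to 0.038), NF-kB signalling (-0.396 to 0.154), pro-inflammatory cytokines (-0.961 to 0.116) and endotoxin sensing (-0.692 to 0.197). Leaving out LPS replicate 3 reversed Il7 (-0.056 to 0.147). For LPS plus PD against control, Il7r reversed with array weights (-0.027) and without control replicate 2 (-0.083, up to 0.197 without another library). For the array weights and the left-out libraries the cause was not tested.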

Other observations

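The tests of LPS replicate 2, of heart muscle and nuclear copies and of other splits of the libraries were chosen after the result was seen. The gene lists of squamous and basal airway epithelium, the nuclear-encoded respiratory chain, cartilage and nuclear mitochondrial copies were also written after the data were examined. The squamous and basal list holds genes already seen to fall, so its count and camera result test nothing and are left out. Single genes of it fell after LPS. Krt8, a keratin of simple epithelium, went from 322, 556 and 379 FPKM in the controls to 89.1, 111 and 125 FPKM in the LPS libraries (adjusted p = 0.0171). Sfn, the 14-3-3 protein of stratified epithelium, differed by -2.11 (adjusted p = 0.0127). The basal keratins Krt5, Krt14 and Krt15 did not pass (adjusted p = 0.0907, 0.128 and 0.0842). Krt5 stood at 13.8, 18.3 and 0.554 FPKM and Krt15 at 28.3, 44.1 and 0.951 FPKM in control replicates 1, 2 and 3, with at most 0.926 and 0.66 FPKM in LPS, so their difference rests on 2 control libraries. The 44 nuclear-encoded respiratory chain genes were all lower after LPS, with none past the threshold (median -0.49, camera adjusted p = 2.5e-06, adjusted p = 0.265 with an estimated correlation).

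Clock and detoxification genes held single changes in lists that camera did not call. After LPS Dbp and Hlf, a pair of transcription factors driven by the circadian clock, fell by 2.14 (adjusted p = 0.0423) and 1.15 (adjusted p = 0.0379), and adjusted over the list alone 2 of 13 clock genes rose and 6 fell (median -0.83, camera adjusted p = 0.181). Of 15 xenobiotic-metabolising enzymes the esterase gene Ces1g fell by 2.18 and Cyp2s1 by 1.43, 5 adjusted over the list alone (median -0.68, camera adjusted p = 0.0594). LPS replicate 2 lay lowest on both lists. List means in LPS replicates 1, 2 and 3 were -0.27, -1.21 and -0.38 for clock genes and -0.21, -1.39 and -0.58 for the enzymes.

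The labels call all mice female. Xist, the RNA of the inactive X chromosome, was at 0.018 to 0.089 FPKM (5 to 27 reads) in the 9 libraries, and the Y-linked genes Ddx3y and Eif2s3y were at 15.4 to 31.9 and 16.5 to 28.5 FPKM. Kdm5d and Uty, also Y-linked, were at 2.19 to 2.88 and 3.26 to 4.19 FPKM. These values contradict the label: by these transcripts all 9 libraries were male. Mitochondrial genes held 3.36%, 7.01% and 4.75% of the reads in control replicates 1, 2 and 3, 2.45%, 2.62% and 1.99% in LPS and 1.32%, 2.01% and 1.80% in LPS plus PD.

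LPS replicate 2 lay 2.74 (log2, median of 70 genes) above the mean of LPS replicates 1 and 3 in cytokine, chemokine and interferon-stimulated genes. Library scaling is argued against, since the gap was 2.75 after quantile normalization. A larger share of neutrophils and monocytes in that piece stays open: markers of both cells had a gap of 2.33, and the gap of the 3 lists exceeded it by 0.41, which is within 2 standard errors (0.325) of 0. That standard error comes from resampling genes, which are not independent. It holds no spread between libraries and cannot decide the question. Markers of some other cells lay lower in LPS replicate 2 than in LPS replicates 1 and 3, with list means of -0.70 against 0.58 and 0.68 for endothelium, -0.39 against 0.564 and 0.545 for alveolar type 1 cells, -1.32 against -0.34 and -0.12 for fibroblasts, -1.28 against -0.14 and -0.13 for smooth muscle and -1.36 against 0.08 and 0.79 for erythroid genes. Markers of several further cells did not. Their list means in LPS replicates 1, 2 and 3 were 0.38, 1.85 and 1.58 for NK and cytotoxic cells and 0.12, 1.14 and 0.25 for dendritic cells. They were -0.26, 0.13 and 0.19 for T cells and -0.29, -0.26 and 0.34 for B cells. These bear on the cell composition of the piece and were not tested. A stronger response or another sampling time was not tested.

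Mitochondrially encoded transcripts were lower with PD than with LPS alone by camera with a preset correlation. None of the 13 genes passed over all genes, and the list was not called with an estimated correlation (adjusted p = 0.585) or by fry (adjusted p = 0.5). Less heart muscle in the piece is argued against, since the heart muscle median was 1.45 higher with PD. A move of reads to 7 nuclear copies is argued against too, since these copies had a median of -1.11. Shared reads that were lost or discarded would lower the copies and the mitochondrial genes together. The copies cannot decide on such a loss, and the treatment of shared reads is not given. A fall of the whole respiratory chain is argued against, since its 44 nuclear-encoded genes had a median of 0.20 (camera adjusted p = 0.00031, adjusted p = 0.499 with an estimated correlation). That median may rest in part on LPS replicate 2 and was not computed without it. In LPS replicates 1, 2 and 3 Ndufa1 stood at 77.3, 25.1 and 62.0 FPKM, while Atp5b stood at 110, 160 and 119 FPKM. The ribosomal RNAs of the mitochondrion differed by -0.02 on average and the 13 other transcripts by -0.87. Other causes, a PD effect among them, were not tested.

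Heart muscle and adipocyte genes were lower after LPS than in control by camera with a preset correlation, and neither list was called with an estimated correlation (adjusted p = 0.384 and 0.609). No adipocyte gene fell over all genes, and that call was lost in 7 of the 9 fits without 1 library. If the LPS pieces held less heart, fat and cartilage-bearing airway, cartilage genes should be lower too, and 3 of 14 cartilage genes were measured, with a median of -2.11 and Chad (-2.76, adjusted p = 0.04) and Cytl1 (-2.11, adjusted p = 0.0304) past the threshold. This is consistent with a difference in what was dissected. It may also bear on the lower ciliated and club cell genes, and a response of these tissues to LPS was not tested apart from it. With PD against LPS no member of these lists passed over all genes. Their medians were above 0: 1.45 for heart muscle (adjusted p = 0.585 with an estimated correlation), 0.745 for the 3 cartilage genes (camera adjusted p = 0.0494, adjusted p = 0.226 with an estimated correlation) and 0.71 for the adipocyte genes (camera adjusted p = 0.0556, not called). A difference in what was dissected is open for the higher heart muscle genes with PD as well.

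Other splits of the 6 libraries of each comparison were counted. For LPS against control 1 of 10 splits, the real one, gave 613 genes and the highest other gave 1. For LPS plus PD against control 1 of 10 gave 128 and the highest other 0. For LPS plus PD against LPS all 10 gave at least the real count of 0, and the highest other gave 1. With 10 splits the share cannot fall below 0.05.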
